A study of Oryza nivara and Oryza rufipogon with 42 samples.

How the data were processed

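Gene expression was measured in the wild rices Oryza nivara and Oryza rufipogon, from 36 libraries of digital gene expression (DGE) and 6 paired-end RNA-seq libraries. DGE reads a short tag cut from the 3' region of each transcript with the enzymes NlaIII and MmeI. Flag leaves at the heading stage, panicles at the heading stage and panicles at the flowering stage were each taken from 6 plants of each species. Per the labels, 3 of the 6 plants of each group were collected in 2009 and 3 in 2010, from accessions of India, Thailand, Nepal and Myanmar grown in a greenhouse. The number in each library title was taken as the plant, and p-values within a tissue concern separate plants as far as those numbers show. Tests between tissues and of the interaction compare organs that partly come from the same plants, and their main model treats these as independent.

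The authors deposited DGE tag counts per gene, and DGE values as TPM, which here means tag counts per 1e6 of a total per library with no division by gene length. Each deposited TPM value times its library's total gave back the deposited count for all 20134 genes, with a largest deviation of 2.04e-10. That total exceeded the sum of the listed genes, so 0.731 to 2.83% of each library's counts lay outside the listed genes. Every listed gene reached 5 TPM in at least 4 libraries, so genes with lower counts had been removed from the table. The authors' RNA-seq values were deposited as RPKM, reads scaled by the length of the gene model and by the mapped reads of the library, for 37497 genes, each above 0 in at least 1 library. Its columns carry the RNA-seq titles without their suffix, and each was taken as the only RNA-seq sample of its species and tissue. Per the labels the authors' notes name BWA, without a version, and edgeR 3.6.8. The genome build and the annotation are not given in the sources used here.

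The DGE counts were used for all tests. Summed counts per DGE library ranged from 1725036 to 4173433. The RPKM files give no read totals, so the RNA-seq depth is unknown and no counting interval was computed from them. The interval given for a median RNA-seq ratio is over genes, by their order, and takes genes as independent. The smallest step of the RPKM values gave only relative depths, from 1 to 1.12 over the 6 libraries. Levels are CPM (counts per 1e6 of the scaled library total) with TMM scaling over all 36 libraries, given as mean ± SD over the 6 plants of a group. A count of 0 over a group allows up to 3 counts, and a fold against it was computed from that floor over the group. With 1 to 3 counts in a group, the ratio is given by its 95% counting interval. Floors and intervals cover counting error only, since PCR copies of a tag are not independent molecules. Pearson's r between libraries of 1 group ranged from 0.505 to 0.908 across genes on the log scale, and no library was a copy of another.

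Species differences were tested within each tissue with edgeR 4.0.16 (R 4.3.3; quasi-likelihood F test, TMM, filterByExpr) as O. nivara minus O. rufipogon, with collection year as an additive term. Year differences are the year term of the same model, as 2010 minus 2009, with species as the other term. Tissue differences and the species by tissue interaction came from 1 model of all 36 libraries with 6 group means and a year term for each tissue. Benjamini-Hochberg adjustment was made over the genes tested, and genes with an adjusted p under 0.05 are called different. Flowering panicles were compared with heading panicles, and heading panicles with flag leaves. Genes detected per library were counted after thinning every library to 1725036 counts and compared by an exact permutation test, two-sided, over the 924 splits of 12 libraries.

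The 15 gene lists were fixed before the data were examined: flowering time, circadian clock, floral organ identity, panicle architecture and shattering, anther and pollen development, meiosis, drought and abscisic acid response, flooding and low oxygen, gibberellin and elongation, heat shock, photosynthesis, chlorophyll breakdown and senescence, defence and phytoalexins, endosperm markers, and housekeeping. They hold 235 entries for 231 loci, of which 190 are in the count table. The files pair no locus number with a gene symbol or a description. Symbols were therefore attached to locus numbers from general knowledge of rice genes before the data were examined and were not checked against an annotation. Lists chosen by gene description were void for the same reason. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, adjusted over the lists of a comparison). Each was repeated with a correlation estimated per list and with fry, which tests whether a list's genes move, on balance, in 1 direction without comparing them with other genes.

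Named genes followed a rule fixed before the data were examined. For each species difference it took the 10 largest fold changes in each direction among called genes with a mean of at least 10 CPM in the higher species and no overlap between the libraries of the species, and up to 4 called members of each list. Members of the flowering time list were open to printing by value. For each tissue difference it took the 5 largest called fold changes in each direction and the 2 members of each list with the smallest p, and for the interaction the 5 smallest p. Of genes without a symbol, only the first 2 in each direction are given. Genes named for the year differences, list members past the threshold only when adjusted over the list alone, and the pollen and anther wall genes shown per library were chosen after their values were seen.

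Title numbers recur across tissues, and they were checked for pairing. Over 26 pairs of libraries with the same number in 2 tissues, the deviations from the group means correlated across genes with r from 0.177 to 0.62. With year also removed, r ranged from -0.0553 to 0.486, and 22 of the 26 libraries matched their own number best. Models with the number as a block were therefore fitted for the tissue differences and the interaction. The main model has no block, since O. nivara flowering and heading panicles share only 2 numbers.

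The tests were tried on simulated counts with the spread of these libraries. At an 8-fold difference edgeR called 82% of the changed genes in flag leaves, 72% in heading panicles and 78% in flowering panicles, and at a 2-fold difference 0, 2 and 0%. False calls by edgeR were 4 of 15260, 3 of 18414 and 1 of 18523 unchanged genes. DESeq2 made 24, 54 and 37 false calls on the same counts. For the interaction, 50% of 8-fold differences were called. A simulated list of 20 genes at 1.5-fold had adjusted camera p-values of 9.23e-05, 0.127 and 0.00185 in the 3 tissues, and 1 other list was called in flag leaves, 0 in the panicles. The simulated genes were drawn independently, so these results cannot show false list calls that come from correlated genes. Other splits of the real libraries gave a median of 1, 2 and 2 lists called in the 3 tissues.

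Alternatives fixed in advance were DESeq2 size factors, DESeq2 1.42.0 (Wald or likelihood ratio test), no filter and a filter of at least 5 CPM in 6 libraries, no year term, each year alone, plants from India alone, all 36 libraries in 1 model, limma-trend on the deposited TPM values, a 2-fold minimum, the block, and estimated list correlations or fry. Thinning to 1 depth, scaling by library totals alone and leaving out the O. nivara flowering panicles 34 and 197 were added after seeing the data. Figures were drawn with matplotlib 3.10.9.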

Results

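The 36 DGE libraries fell into 6 groups of 6 plants, given by species (O. nivara or O. rufipogon) and tissue (flag leaf, heading panicle or flowering panicle). Summed counts were 1725036 to 2712054 in the 18 libraries collected in 2009, with a median of 2242288.5, and 2677440 to 4173433 in the 18 of 2010, with a median of 3835948. By group they ranged from 2159550 to 4173433 in O. nivara flag leaves, from 1725036 to 3944555 in its heading panicles and from 2250794 to 4044371 in its flowering panicles. In O. rufipogon they ranged from 1873240 to 4154876, from 1951781 to 4164766 and from 2021814 to 4094708 in the same order. Photosynthesis genes took 15.2% ± 3.03 (SD, n = 6) of the counts in O. nivara flag leaves and 1.42% ± 1.19 in its heading panicles. Collection year explained 95.3% of the first principal component in flag leaves, 84.6% in heading panicles and 50.9% in flowering panicles. The median share of a gene's variance that went with species was 5.86, 5.56 and 9.5% in the same order, against 18.5, 19 and 15.6% for year. Symbols beside locus numbers are from general knowledge, since the files pair no locus with a name.

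The comparison of the species asks which genes differ in expression between 2 wild rices that live in different habitats, O. nivara as an annual and O. rufipogon as a perennial. In flag leaves, LOC_Os08g14195 was at 83.3 ± 47.4 CPM (SD, n = 6) in O. nivara and 3.72 ± 2.20 in O. rufipogon, a log2 difference of 4.58 (SE 0.53, adjusted p = 0.00247). LOC_Os06g29844 was at 27.3 ± 12.1 against 4.97 ± 2.08 CPM, a log2 difference of 2.45 (SE 0.40, adjusted p = 0.0202). Lower in O. nivara were LOC_Os11g32560, with 3 counts in its 6 libraries against 2450 in O. rufipogon (201 ± 101 CPM), and LOC_Os07g39060, with 2 counts against 1157 (95.2 CPM). The counting intervals of these ratios ran from 289 to 4100 and from 166 to 4960. In RNA-seq the ratio of LOC_Os07g39060 was near 0 on the log2 scale (-0.06), with RPKM of 0 and 0.0452, while that of LOC_Os11g32560 was -4.76.

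In all, 31 of 15480 genes were called different in flag leaves, 5 higher and 26 lower in O. nivara, and each differed by at least 2-fold. No list was called by camera in this tissue, where the lowest adjusted p was 0.415 for chlorophyll breakdown and senescence. Within that list 2 of 6 genes were higher in O. nivara when adjusted over the list alone, and 0 when adjusted over all genes. They were OsNAP (LOC_Os03g21060), a NAC factor of leaf senescence, at 43.7 ± 14.9 against 8.67 ± 6.38 CPM (log2 2.31, SE 0.43, adjusted p = 0.0582 over all genes), and PAO (LOC_Os03g05310), an enzyme of chlorophyll breakdown, at 123 ± 38.6 against 63.9 ± 24.0 CPM. The fry test gave an adjusted p of 0.0182 for the list. Of the flowering time genes, Hd3a (LOC_Os06g06320) stood at 14.9 ± 18.3 CPM in O. nivara and 3.54 ± 8.39 in O. rufipogon, which was not past the threshold. OsMADS15 (LOC_Os07g01820), a MADS-box gene of the floral transition, stood at 106 ± 69.2 against 39.5 ± 32.3 CPM and was not called. Within years edgeR called 12 genes among the plants of 2009, of which 4 were among the 31. It called 0 among those of 2010, where 1235 genes had an unadjusted p under 0.05. DESeq2 called 406.

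In heading panicles the largest differences were in a pair of neighbouring locus numbers that were high in O. nivara. LOC_Os10g05930 was at 594 ± 494 CPM (SD, n = 6) in O. nivara and 0.225 in O. rufipogon (log2 11.15, SE 1.31, adjusted p = 0.00407). LOC_Os10g05910 was at 380 ± 398 CPM, against 2 counts in the 6 O. rufipogon libraries (ratio interval 1150 to 34300, adjusted p = 0.009). Both were low in 1 O. nivara library, plant 52, at 4.89 and 0.932 CPM, where the other 5 held at least 443 and 114. Lower in O. nivara were LOC_Os01g35330, with 1 count against 1697 (ratio interval 245 to 53900), and LOC_Os11g32560, with 2 counts against 1339 (56.3 CPM, ratio interval 150 to 4470). LOC_Os01g35330 was uneven in O. rufipogon heading panicles, from 0.682 CPM in plant 199 to 254 in plant 95, beside 0.375 in O. nivara plant 33. In flowering panicles O. rufipogon plant 230 held 0.419 CPM of it, less than the 1.01 of O. nivara plant 34. Photosynthesis genes tended lower in O. nivara: the list's median log2 difference was -0.65 over 35 genes and its adjusted camera p was 2.61e-08, while p = 0.112 with an estimated correlation. Of these genes 0 were called over all genes by edgeR and 3 when adjusted over the list alone, among them LHCB1.3 (LOC_Os01g52240), a light-harvesting protein, at 268 ± 269 against 894 ± 718 CPM.

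Starch and storage genes of the endosperm had a median log2 difference of -0.66 over 6 genes in heading panicles (adjusted camera p = 0.00968, and p = 0.0426 but adjusted p = 0.639 with an estimated correlation). SSIIa (LOC_Os06g12450), a starch synthase, was at 7.31 ± 2.37 against 19.4 ± 8.21 CPM and was one of 2 members lower when adjusted over the list alone. Of 14 floral organ identity genes, OsMADS5 (LOC_Os06g06750) was higher and OsMADS3 (LOC_Os01g10504) and OsMADS7 (LOC_Os08g41950) were lower in O. nivara when adjusted over the list alone. OsMADS5, a gene of the spikelet, was at 62.7 ± 24.8 against 26.0 ± 8.24 CPM. Altogether 30 of 18634 genes were called, 6 higher and 24 lower in O. nivara. The plants of 2009 alone gave 31, of which only 6 were among the 30. Those of 2010 alone gave 11, of which 4 were among the 30. The heading panicles of both species varied widely in ACOS12 (LOC_Os04g24530), a pollen wall gene of the tapetum, which was at 449 ± 325 CPM in O. nivara and 850 ± 1588 in O. rufipogon. It was close to 0 in O. nivara plant 52 and low in 4 of 6 O. rufipogon plants. DESeq2 called 512 genes.

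**Figure D1:**
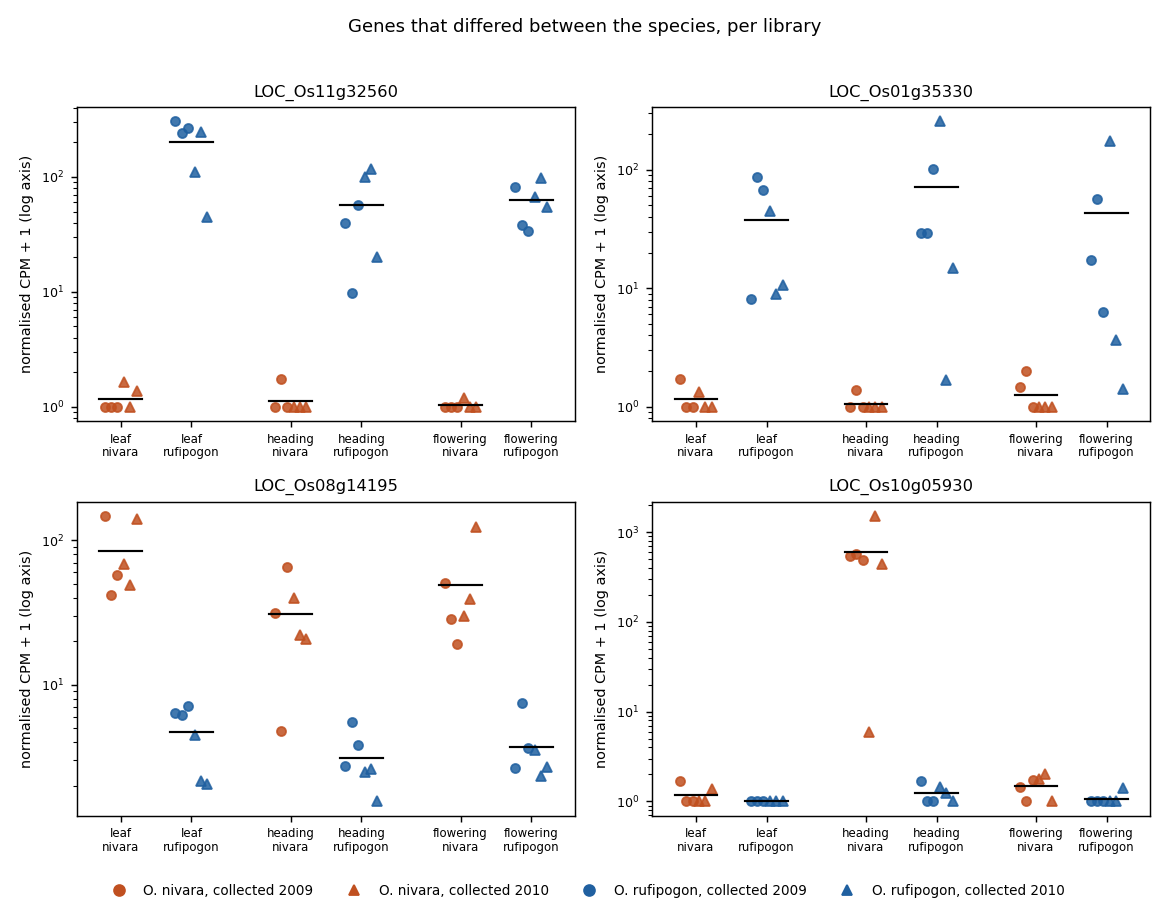
Normalised CPM plus 1 on a log axis for 4 called genes, 1 point per library, by tissue and species, with circles for plants of 2009, triangles for plants of 2010 and a bar at the mean of 6. LOC_Os11g32560 held 3, 2 and 1 counts over the 6 O. nivara libraries of the 3 tissues, and LOC_Os10g05930 was high in 5 of 6 O. nivara heading panicles.

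In flowering panicles, genes of anther and pollen development were lower in O. nivara as a group, with a median log2 difference of -1.39 over 17 genes (adjusted p = 3.01e-07 by camera and 0.0165 by fry). With an estimated correlation p = 0.0311, and adjusted p = 0.233. One of them was called over all genes and 8 were lower when adjusted over the list alone. TIP2 (LOC_Os01g18870), a regulator of tapetum development, was at 1.65 ± 1.67 CPM (SD, n = 6) in O. nivara and 10.3 ± 7.77 in O. rufipogon (log2 -2.65, SE 0.49, adjusted p = 0.0324). TDR (LOC_Os02g02820), another tapetum regulator, was at 8.64 ± 10.9 against 68.5 ± 76.0 CPM, and OsINV4 (LOC_Os04g33720), a cell wall invertase of anthers, at 14.8 ± 15.3 against 221 ± 215. The list took 0.0331% ± 0.0208 of the counts in O. nivara and 0.255% ± 0.273 in O. rufipogon. The pollen MADS-box genes OsMADS62, OsMADS63 and OsMADS68 were at most 4.36 CPM in O. nivara plants 34 and 197, and at least 7.94 in every other flowering panicle.

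Endosperm genes were also lower in O. nivara flowering panicles, with a median log2 difference of -1.57 over 5 genes and 2 of them lower when adjusted over the list alone (adjusted p = 0.0113 by camera and 0.0133 by fry). With an estimated correlation p = 0.0144, and adjusted p = 0.215. BEIIb (LOC_Os02g32660), a starch branching enzyme, was at 129 ± 129 against 391 ± 96.4 CPM. Photosynthesis genes had a median log2 difference of 0.68 (adjusted camera p = 0.00168, but p = 0.344 with an estimated correlation) and heat shock genes of 0.77 (0.0113, but p = 0.151). None of the 35 and 12 genes was called by edgeR over all genes or over the list alone. The heat shock list had an adjusted camera p of 0.0658 without plants 34 and 197. OsLEA3 (LOC_Os05g46480), a late embryogenesis abundant gene, was lower in O. nivara, at 0.292 ± 0.257 against 13.7 ± 14.8 CPM (log2 -5.25, SE 0.94, adjusted p = 0.0299). In the RNA-seq pair its log2 ratio was -0.39, with RPKM of 7.67 in O. nivara and 10.3 in O. rufipogon, against a DGE log2 ratio of -3.84 in the same plants. Of 9 genes of panicle architecture and shattering 3 were higher in O. nivara when adjusted over the list alone, including qSH1 (LOC_Os01g62920), a homeobox gene of the abscission layer, at 37.0 ± 17.9 against 18.6 ± 10.8 CPM, and SHAT1 (LOC_Os04g55560), at 69.7 ± 34.8 against 30.5 ± 12.7 CPM. Of 9 defence genes 3 were higher and 1 was lower on the same basis, with CPS2 (LOC_Os02g36210), a diterpene synthase of phytoalexin production, at 29.8 ± 22.7 against 5.84 ± 5.76 CPM.

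Among genes without a symbol in flowering panicles, LOC_Os07g36700 was at 103 ± 104 against 1.74 ± 1.56 CPM (log2 5.54, SE 0.95, adjusted p = 0.0266) and LOC_Os06g08640 at 14.5 ± 20.7 against 0.257 CPM (log2 5.20, SE 1.09, adjusted p = 0.0424). Lower in O. nivara were LOC_Os11g32560, with 1 count against 1279 (61.5 ± 25.2 CPM in O. rufipogon, ratio interval 208 to 45800), and LOC_Os05g03240, with 1 count against 896 (46.3 ± 47.7 CPM, ratio interval 157 to 34500). In total 237 of 18743 genes were called, 78 higher and 159 lower in O. nivara, each by at least 2-fold. The plants of 2009 alone gave 13, with 3 among the 237, and those of 2010 alone gave 9, with 4 among the 237. DESeq2 called 1986 over both years. Leaving out a pair of the 6 O. nivara libraries gave between 1 and 377 calls, with 23 when the pair was 34 and 197, and TIP2, OsLEA3 and LOC_Os05g03240 then had adjusted p of 0.0523, 0.1 and 0.0523, with log2 differences of -2.19, -5.65 and -8.52 against -2.65, -5.25 and -8.87 with all 6. TIP2 was also not called without a year term (adjusted p = 0.14) or with all 36 libraries in 1 model (adjusted p = 0.101), and LOC_Os06g08640 was not called by limma-trend (adjusted p = 0.0759).

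**Figure D2:**
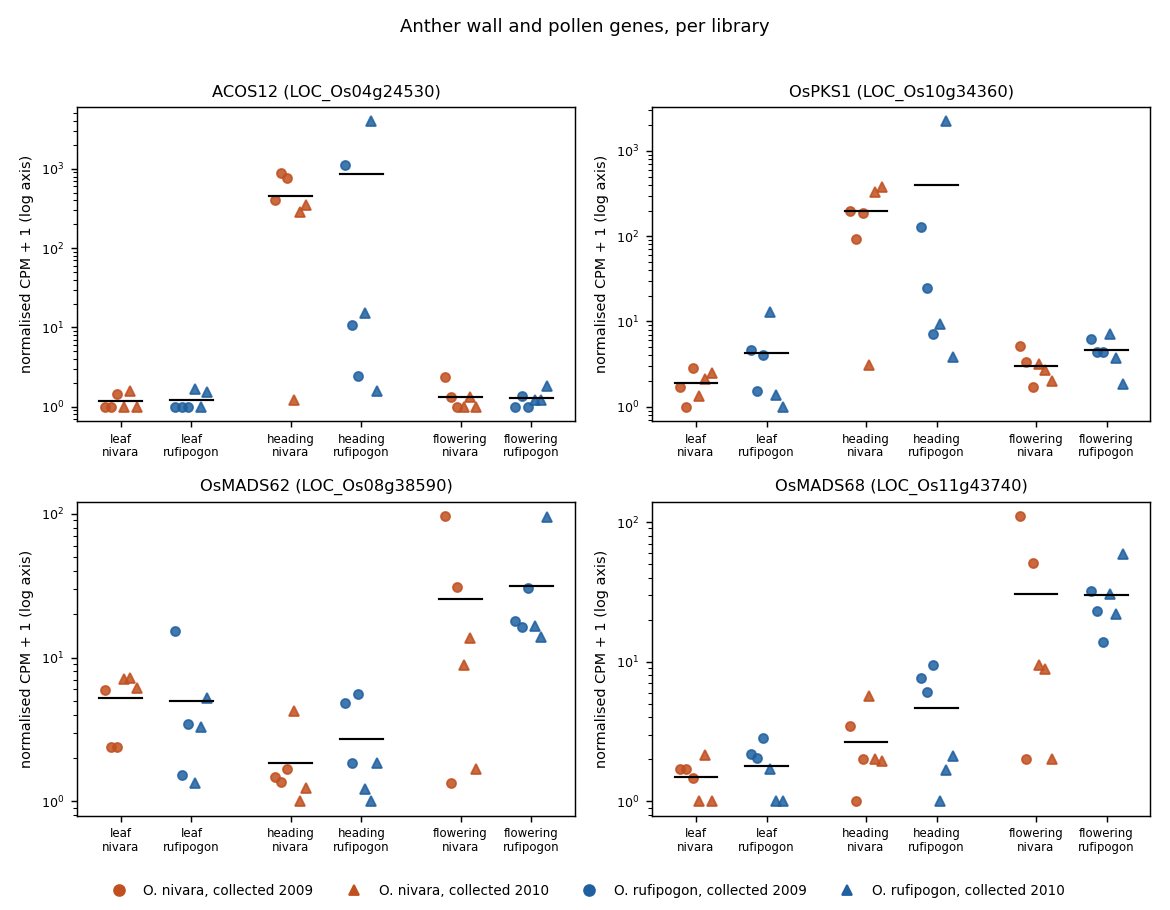
Normalised CPM plus 1 on a log axis for the tapetum genes ACOS12 and OsPKS1 and the pollen genes OsMADS62 and OsMADS68, 1 point per library, by tissue and species, with circles for 2009, triangles for 2010 and a bar at the mean of 6. ACOS12 averaged 449 CPM in O. nivara heading panicles and 0.342 in its flowering panicles, and OsMADS62 and OsMADS68 were at 1.01 CPM or less in O. nivara flowering panicles 34 and 197.

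The other lists were not called in the species differences. Their adjusted camera p-values ran from 0.415 to 0.934 in flag leaves, from 0.0847 to 0.966 in heading panicles and from 0.136 to 0.958 in flowering panicles, with the clock list lowest in heading panicles. Of the flowering time list 19, 18 and 19 genes were tested in the 3 tissues, of the clock list 9 in each, and of the housekeeping list 5 in each, and edgeR called 0 of them. Meiosis genes, flooding genes and gibberellin genes likewise had 0 calls over all genes. Over the list alone 1 of these lists' genes was past the threshold, the gibberellin gene GA2ox1 (LOC_Os05g06670), at 124 ± 104 CPM in O. nivara and 551 ± 425 in O. rufipogon flowering panicles.

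Species differences recurred across tissues. Flag leaves and heading panicles shared 1 gene higher and 11 lower in O. nivara, where independent lists would share 0.00108 and 0.028. Heading and flowering panicles shared 2 and 19 (0.0162 and 0.185), and flag leaves and flowering panicles 1 and 14 (0.0168 and 0.126). No gene called in both tissues of a pair went in opposite directions. LOC_Os08g14195 was higher in O. nivara in all 3 tissues, and 10 genes, LOC_Os11g32560 among them, were lower in all 3. The tissues share up to 11 plants, so these overlaps are not independent. The log2 differences of the tissues correlated across genes with r = 0.509, 0.618 and 0.409 in the same order, and genes are not independent replicates. A sequence variant that removes the counted DGE tag would also recur in every tissue, so recurrence alone does not show that transcript levels differ. Of the 11 genes called in all 3 tissues, LOC_Os11g32560 had RNA-seq log2 ratios of -4.76 in flag leaf and -3.01 in heading panicle. LOC_Os01g12540, named after its values were seen, had 0.08 and -0.18, with RPKM of 3.10 to 4.59. These are examples, and the 11 were not tested as a set.

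A difference between tissues in the species difference itself was detected for 3 of 20134 genes, with 1714 at an unadjusted p under 0.05. LOC_Os01g65850 was at 2.32 ± 1.0 CPM in O. nivara and 101 ± 81.1 in O. rufipogon heading panicles, and at 19.5 ± 16.1 against 14 ± 7.57 in flag leaves (adjusted p = 0.0424). Its RNA-seq log2 ratio was -0.16 in heading panicle (RPKM 1.23 and 1.48), against a DGE ratio of -4.80 in the same plants. In flowering panicle it was -0.46 against -3.80. The RPKM there were 0.0351 and 0.422, and adding 1 to such low values draws their ratio towards 0. LOC_Os02g17304 was at 3.37 ± 1.51 against 16.2 ± 4.82 CPM in flag leaves and 6.77 ± 2.30 against 4.44 ± 2.56 in heading panicles (adjusted p = 0.0138). LOC_Os02g01700 was at 0.202 ± 0.314 against 4.68 ± 5.24 CPM in flag leaves and 45.2 ± 34.7 against 26.5 ± 27.4 in heading panicles (adjusted p = 0.0138). By p-value LOC_Os02g01700 and LOC_Os02g17304 were the first 2 IDs for this test. LOC_Os01g65850 came after them, so it fell outside the naming rule and was named after its values were seen. DESeq2 called 79. The model with title number as a block called 3, of which 2 are among these genes.

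Genes detected per library did not differ detectably between the species. At 1725036 counts per library there were 18206 ± 525 genes (SD, n = 6) in O. nivara and 18107 ± 491 in O. rufipogon flag leaves (exact permutation p = 0.742). The counts were 19204 ± 201 and 19373 ± 262 in heading panicles (exact p = 0.229), and 19380 ± 139 and 19486 ± 278 in flowering panicles (exact p = 0.403). Adjusted over the 3 tissues the p-values were 0.742, 0.604 and 0.604. Within years the difference of O. nivara minus O. rufipogon was -405 genes in 2009 and 603 in 2010 in flag leaves, -320 and -20 in heading panicles, and -372 and 161 in flowering panicles.

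Heading panicles differed from flag leaves in the genes that build flowers and in those of photosynthesis. In O. nivara 13 of 14 floral organ identity genes were higher in heading panicles, with a median log2 difference of 5.68 (adjusted camera p = 9.2e-15, and p = 0.000105 with an estimated correlation), and in O. rufipogon 13 of 14, with a median of 5.19 (1.86e-17, and p = 4.58e-05). OsMADS16 (LOC_Os06g49840), a gene of petal and stamen identity, rose from 9.0 ± 4.88 to 503 ± 377 CPM (SD, n = 6) in O. nivara and from 13.8 ± 10.0 to 856 ± 491 in O. rufipogon. All 35 photosynthesis genes were lower in O. nivara heading panicles and 34 of 35 in those of O. rufipogon, with median log2 differences of -4.60 and -3.82 (p = 0.000811 and p = 0.00128 with an estimated correlation). GAPB (LOC_Os03g03720), a chloroplast dehydrogenase of the Calvin cycle, was at 82.4 ± 39.7 against 3231 ± 1395 CPM in O. nivara.

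Anther and pollen genes were higher in heading panicles than in flag leaves, 17 of 24 in O. nivara and 18 of 24 in O. rufipogon (adjusted camera p = 0.000308 and 0.000238, but p = 0.0556 and p = 0.0517 with an estimated correlation). RTS (LOC_Os01g70440), an anther gene of the tapetum, was at 4667 ± 4079 CPM in O. rufipogon heading panicles against 2 counts in its flag leaves (ratio interval 8160 to 243000). Clock genes were lower in panicles, 6 of 9 in each species (adjusted camera p = 0.000519 and 0.00118, adjusted p = 0.0242 and adjusted p = 0.0399 with an estimated correlation), with OsPRR37 (LOC_Os07g49460) at 22.7 ± 15.5 against 186 ± 77.1 CPM in O. nivara. Chlorophyll breakdown genes were lower in 5 of 6 and 4 of 6 (7.06e-05 and 0.00037, with adjusted p = 0.0242 but in O. rufipogon adjusted p = 0.0551 with an estimated correlation). Flowering time genes were lower in 9 and 7 of 20 and higher in 2 and 1 (0.0304 and 0.0181, but adjusted p = 0.0741 and adjusted p = 0.0604 with an estimated correlation). Genes of panicle architecture and shattering were higher in 4 and 5 of 9 (0.0243 and 0.0713, adjusted p = 0.0366 and adjusted p = 0.0978 with an estimated correlation), with SH5 (LOC_Os05g38120), a homeobox gene of shattering, at 25.9 ± 18.0 against 0.910 ± 1.07 CPM in O. nivara.

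The remaining lists were not called by camera between heading panicles and flag leaves (adjusted p from 0.0587 to 0.591 in O. nivara and from 0.143 to 0.356 in O. rufipogon), and their members went both ways or few passed the test. Drought genes had 3 higher and 6 lower of 22 in O. nivara and 9 and 8 in O. rufipogon, with OsNAC6 (LOC_Os01g66120) at 124 ± 113 against 2393 ± 2267 CPM in O. nivara. Defence genes had 1 higher and 9 lower of 13 and 2 and 4, and heat shock genes 7 higher and 1 lower of 13 and 3 and 0. Endosperm genes had 3 higher and 1 lower of 6 in each species, gibberellin genes 2 higher of 7 in each, and meiosis genes 2 and 1 higher of 4. Flooding genes had 1 higher and 1 lower of 7 and 2 and 1, with ADH1 (LOC_Os11g10480), an alcohol dehydrogenase, at 173 ± 118 against 29.7 ± 22.9 CPM in O. nivara. Housekeeping genes had 3 and 2 higher of 5. Among genes without a symbol, LOC_Os11g02350 was at least 460-fold higher in O. nivara heading panicles than in its flag leaves, where it had 0 counts, and LOC_Os11g10320 was at 0.272 ± 0.56 against 547 ± 655 CPM.

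In all, 9405 of 20134 genes were called between heading panicles and flag leaves in O. nivara, 5301 higher and 4104 lower in panicles, and 8575 in O. rufipogon, 4814 higher and 3761 lower. With title number as a block the totals were 9386 and 9173. TMM scaling left the median gene 0.18 and 0.20 higher in panicles on the log2 scale, and scaling by library totals alone 0.80 and 0.91, with splits of 8299 higher and 2416 lower in O. nivara and 8810 and 2184 in O. rufipogon. The 10 most abundant genes took 12.5% ± 2.28 of the counts in O. nivara flag leaves and 5.18% ± 1.04 in its heading panicles.

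From heading to flowering panicles most of the called anther and pollen genes fell. In O. nivara 17 of 24 anther and pollen genes fell and 2 rose (adjusted camera p = 3.74e-08, and p = 0.00648 with an estimated correlation), and in O. rufipogon 11 fell and 2 rose (0.00583, but p = 0.115). ACOS12 fell from 449 ± 325 to 0.342 ± 0.530 CPM (SD, n = 6) in O. nivara (log2 -10.44, SE 1.89, adjusted p = 0.000584) and from 850 ± 1588 to 0.279 ± 0.311 in O. rufipogon (log2 -11.39, SE 1.94, adjusted p = 0.000784). The 2 that rose in each species were OsMADS62 (LOC_Os08g38590; log2 4.29 and 4.60) and OsMADS68 (LOC_Os11g43740; log2 3.42 and 3.64), MADS-box genes of late pollen. Photosynthesis genes rose in 29 of 35 in O. nivara (adjusted camera p = 1.24e-29, p = 0.00218 with an estimated correlation) and in 5 of 35 in O. rufipogon (4.06e-05, but p = 0.183). The Rubisco small subunit gene RBCS4 (LOC_Os12g19470) rose from 808 ± 776 to 5195 ± 3016 CPM in O. nivara and from 836 ± 557 to 3113 ± 2192 in O. rufipogon. Whether these changes differ between the species was tested by gene in the interaction of these tissues, where edgeR called 0 genes (935 at an unadjusted p under 0.05).

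Defence genes rose in 4 of 13 in O. nivara (adjusted camera p = 0.00209, p = 0.0329 but adjusted p = 0.123 with an estimated correlation), with CPS2 going from 0.730 ± 0.785 to 29.8 ± 22.7 CPM, and in 2 of 13 in O. rufipogon. Chlorophyll breakdown genes rose in 3 of 6 and 1 of 6 (0.000499 and 0.0811, but adjusted p = 0.0831 and adjusted p = 0.581 with an estimated correlation), with NOL (LOC_Os03g45194), a chlorophyll b reductase, going from 6.88 ± 2.62 to 31.2 ± 11.2 CPM in O. nivara. The clock list had 1 gene of 9 higher in O. nivara (0.0384, but p = 0.0559 with an estimated correlation) and 0 called by edgeR in O. rufipogon. The heat shock list had a median log2 difference of -1.18 in O. rufipogon with 0 of 13 genes called by edgeR (0.00676, but p = 0.136 with an estimated correlation). BEIIb rose from 92.8 ± 95.0 to 391 ± 96.4 CPM in O. rufipogon, as 1 of 6 endosperm genes in each species. No other list was called by camera, with adjusted p from 0.0798 to 0.924 in O. nivara and from 0.186 to 0.973 in O. rufipogon. Among genes without a symbol, LOC_Os08g38250 had 0 counts in heading panicles of either species and was at least 1470-fold higher in flowering panicles of O. nivara and at least 2180-fold higher in those of O. rufipogon. LOC_Os10g05910 had 2 counts in O. nivara flowering panicles against 6461 in heading panicles (ratio interval 992 to 29600).

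Of 20134 genes 2604 were called between flowering and heading panicles in O. nivara, 1371 higher and 1233 lower in flowering panicles, and 1661 in O. rufipogon, 843 higher and 818 lower. With title number as a block the totals were 46, with 43 higher and 3 lower, and 1796, with 1069 higher and 727 lower. The O. nivara panicles share only 2 numbers, and with that block ACOS12 had a log2 difference of -11.51 and an adjusted p of 0.144. RBCS4 was then not called in O. nivara (log2 3.52, adjusted p = 0.0678) or in O. rufipogon (log2 1.83, adjusted p = 0.0504), which shares 5 numbers, against log2 3.29 and 2.00 without the block. CPS2, NOL, LOC_Os08g38250 and LOC_Os10g05910 also lost their calls in O. nivara with the block, at log2 3.83, 2.06, 9.11 and -12.40 with it and 5.56, 2.16, 10.97 and -11.28 without. Without O. nivara plants 34 and 197 the O. nivara total was 1651, with 1042 higher and 609 lower.

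The comparison of collection years describes the one batch that the labels give. Its plants, depth and any sequencing batch differ together with year, and the genes named for it were chosen after their values were seen. Clock genes differed in every tissue. The morning gene OsLHY (LOC_Os08g06110) was at 2125 CPM in 2010 and 519 in 2009 in flag leaves (log2 2.55, SE 0.76, adjusted p = 0.026). It was at 276 against 60.2 CPM in heading panicles and 433 against 117 in flowering panicles. The evening gene OsGI (LOC_Os01g08700) went the other way, at 38.0 ± 35.1 against 596 ± 312 CPM in flag leaves (log2 -4.34, SE 0.58, adjusted p = 0.00042), 25.5 against 224 in heading panicles and 42.5 against 165 in flowering panicles. OsPRR1, OsFKF1 and OsPRR95 were also lower in 2010 in all 3 tissues. Of the 9 clock genes 2 were higher and 5 lower in 2010 in each tissue (adjusted camera p = 0.0495, 0.0795 and 0.0129, but adjusted p = 0.513, adjusted p = 0.526 and adjusted p = 0.285 with an estimated correlation).

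**Figure D3:**
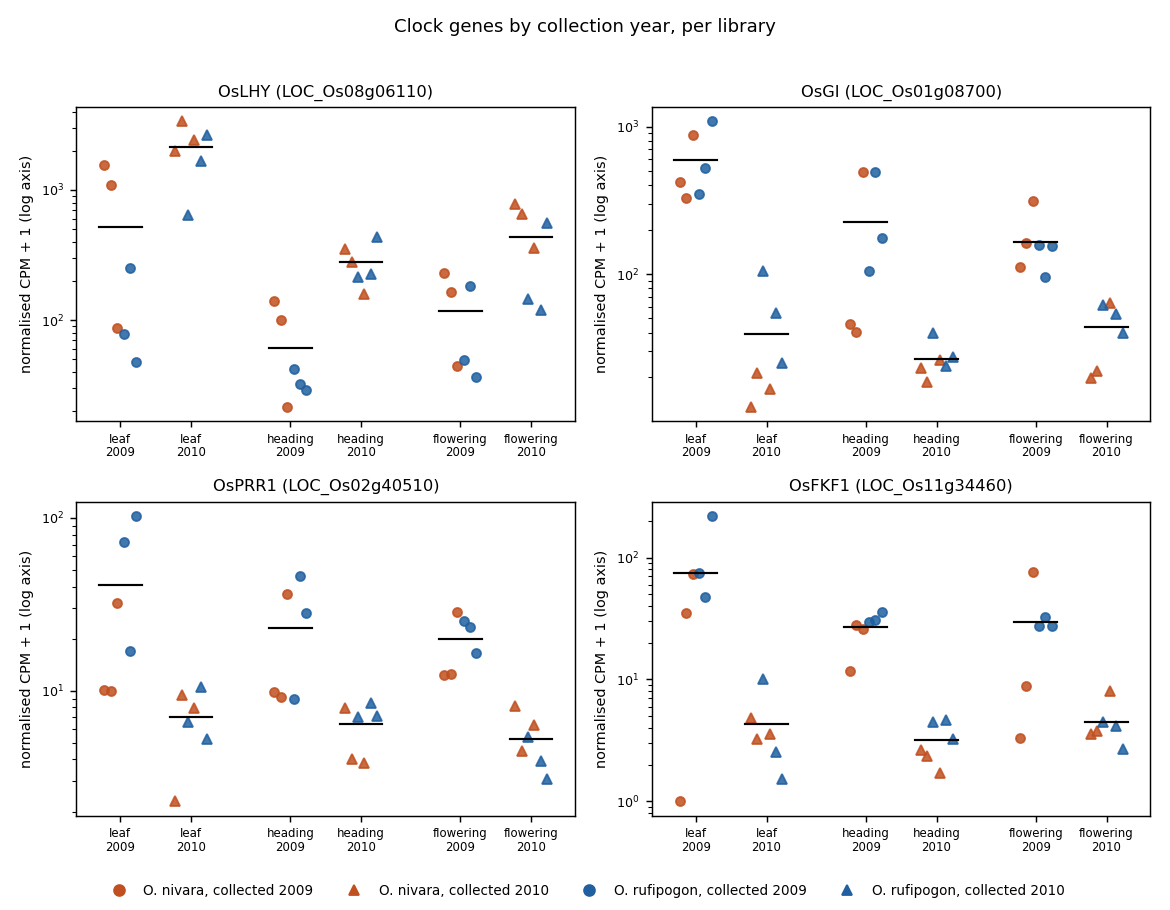
Normalised CPM plus 1 on a log axis for 4 clock genes, 1 point per library, by tissue and collection year, with colours for species and a bar at the mean of 6. OsLHY averaged 2125 CPM in flag leaves of 2010 and 519 in those of 2009, and OsGI 38.0 and 596.

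Drought and abscisic acid genes were lower in 2010 in 8 of 18, 10 of 20 and 9 of 22 genes in flag leaves, heading panicles and flowering panicles (adjusted camera p = 0.0495, 4.23e-05 and 0.000421, but adjusted p = 0.655, adjusted p = 0.238 and adjusted p = 0.285 with an estimated correlation). DREB1C (LOC_Os06g03670), a cold and dehydration response factor, was at 2.62 ± 2.08 CPM in 2010 and 321 ± 220 in 2009 in heading panicles, and at 1.45 ± 1.0 against 147 ± 62.4 in flowering panicles. OsNAC6 was at 588 ± 222 against 3687 ± 1414 CPM in flag leaves. Photosynthesis genes were higher in 2010 in 27 of 35 in heading panicles (adjusted camera p = 2.23e-17, but adjusted p = 0.238 with an estimated correlation), in 7 of 35 in flowering panicles (0.001, but p = 0.334) and in 9 of 35 in flag leaves, where 1 was lower. LHCB5 (LOC_Os11g13890), a light-harvesting protein, was at 1370 ± 616 against 35.3 ± 26.4 CPM in heading panicles. SD1 (LOC_Os01g66100), a gibberellin oxidase of stem elongation, was higher in 2010 in all 3 tissues, at 22.0 against 3.15, 15.9 against 1.98 and 16.7 against 1.85 CPM. The gibberellin list was called in flowering panicles (0.0343, p = 0.0285 but adjusted p = 0.285 with an estimated correlation), as was heat shock (0.0321, but p = 0.206). No other list was called by camera, with adjusted p of at least 0.078 in flag leaves, 0.185 in heading panicles and 0.155 in flowering panicles. The year calls numbered 3946 in flag leaves (2076 higher in 2010, 1870 lower), 4656 in heading panicles (2349 and 2307) and 3326 in flowering panicles (1792 and 1534). In flag leaves TMM scaling over all 36 libraries left the median gene 0.14 higher in 2010 on the log2 scale. In the model of the flag leaf libraries alone, which gave the calls, the median log2 difference was -0.03.

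The 6 RNA-seq libraries were set beside DGE libraries of the same title number and tissue to compare the assays. The design text gives 1 individual per species for the 3 tissues, while the O. nivara titles are 40 for flag leaf and flowering panicle and 39 for heading panicle. Both tables held 19770 genes, and 364 DGE genes were absent from the RNA-seq table. Across genes, log2 levels correlated with a median Pearson r of 0.782 (0.7 to 0.838 over 6 libraries), and genes are not independent replicates. The log2 ratio of the species correlated with r = 0.624 in flag leaf, 0.742 in heading panicle and 0.563 in flowering panicle, with 1 library per species and tissue and so without a test. Of called genes with an RNA-seq value above 0, 24 of 27 went the same way in flag leaves, 23 of 27 in heading panicles and 205 of 225 in flowering panicles. In RNA-seq 11, 7 and 105 of these genes were within 2-fold. Median log2 ratios in the DGE direction were 1.86, 2.05 and 1.11 in RNA-seq, against 2.86, 3.68 and 1.71 in DGE of the same plants. Smaller ratios in RNA-seq can come from the selection of these genes by their DGE differences. Adding 1 draws genes with low values together, but 1 was added to RPKM and TPM alike. How much either contributes was not tested. LOC_Os10g05930 had an RPKM of 319 in the O. nivara heading panicle and 0.0384 in that of O. rufipogon. LOC_Os01g35330 had RPKM of 0, 0.202 and 0.151 in O. nivara and 50.6, 51.6 and 91.8 in O. rufipogon in flag leaf, heading panicle and flowering panicle.

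**Figure D4:**
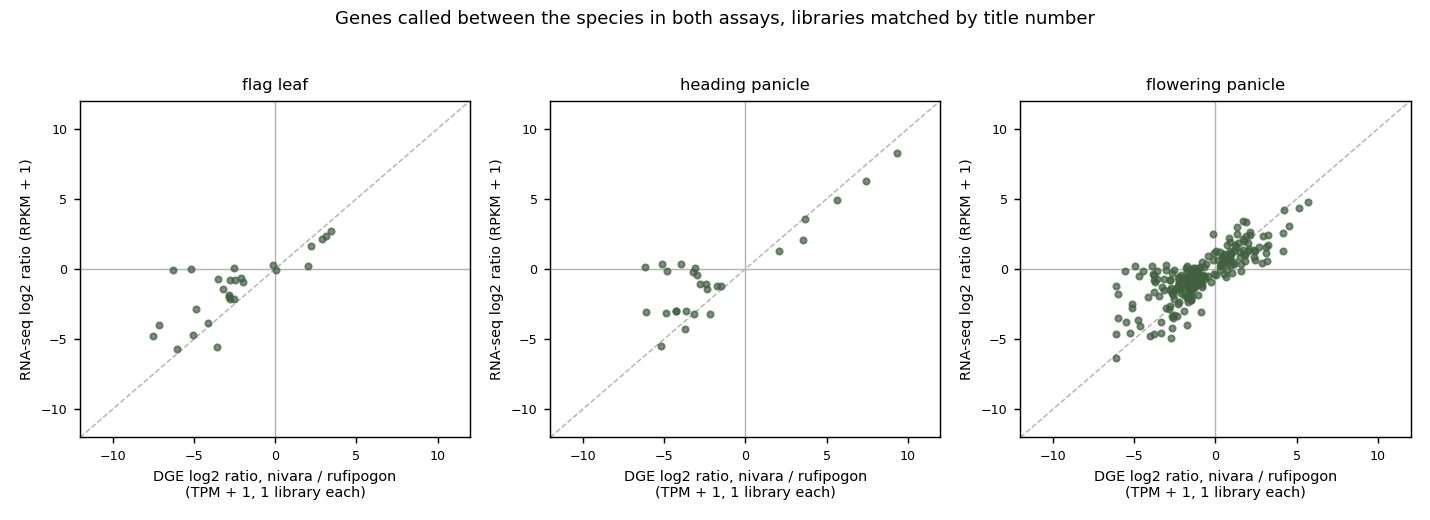
Log2 ratio of O. nivara over O. rufipogon from RNA-seq (RPKM plus 1) against that from DGE (TPM plus 1), 1 point per gene called between the species and above 0 in RNA-seq, with 1 library per species and tissue and the dashed line at equal ratios. Points lie in the same direction for 24 of 27 genes in flag leaf, 23 of 27 in heading panicle and 205 of 225 in flowering panicle.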

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

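The prediction for left-out pairs of O. nivara flowering panicles was set before its result was seen. The other tests of explanations in this part, the splits of the libraries included, were chosen after the results were seen.

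Single libraries stood far from the other 5 of their group in gene levels that matter for the named species differences. O. nivara heading panicle 52 held 0.932 CPM of LOC_Os10g05910 and 4.89 of LOC_Os10g05930, where the next lowest libraries held 114 and 443. O. rufipogon flag leaf 49 held 20.7 CPM of the flowering time gene Hd3a (LOC_Os06g06320), with the next at 0.597, and 0.0511% of its counts in flooding genes, with the next at 0.0106%. In 5 groups a gene close to absent had its few counts in 1 library: LOC_Os01g35330 at 0.375 and LOC_Os11g32560 at 0.75 CPM in O. nivara heading panicle 33, LOC_Os10g05910 at 0.455 in O. rufipogon heading panicle 199, and LOC_Os11g32560 and LOC_Os05g03240 at 0.198 each in O. nivara flowering panicle 52, with the others at 0.

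The share of counts in flowering time genes was 0.228% in O. nivara flowering panicle 34 (next 0.151%) and 0.186% in O. nivara heading panicle 39 (next 0.128%). Housekeeping genes took 0.169% in O. rufipogon flowering panicle 230 (next 0.312%) and 0.51% in O. nivara heading panicle 33 (next 0.26%). Heat shock genes took 0.112% in O. rufipogon heading panicle 49 (next 0.23%). Counts outside the listed genes were 2.32% in O. nivara flag leaf 52 (next 1.22%) and 2.38% in O. rufipogon flag leaf 49 (next 1.3%). O. nivara flowering panicle 52 had the highest total of its group, 4044371 (next 2751388), and the most genes with a count, 19881 (next 19580). Genes with a count numbered 19683 in O. nivara heading panicle 52 (next 19430) and 19324 in O. rufipogon flowering panicle 230 (next 19717). In all 20 of 148 groups of 6 values held such a library. Chance gives about 1 in 20 for values without ties, which leaves out the 5 groups above with counts in 1 library and 0 in the others, as these stand out by construction.

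The species difference itself differed between tissues for LOC_Os02g17304 (adjusted p = 0.0138), LOC_Os02g01700 (adjusted p = 0.0138) and LOC_Os01g65850 (adjusted p = 0.0424) by edgeR. LOC_Os01g65850 was lower in O. nivara in both panicle stages, at 2.32 against 101 and 2.70 against 47.8 CPM, and not called in flag leaves. In RNA-seq its log2 ratio was only -0.16 in heading panicle. The -0.46 in flowering panicle rests on RPKM under 1 in both species, where adding 1 brings any pair within 2-fold. Chance is not excluded for the number of such genes. Of 40 labellings 3 gave as many, the real one included, with 3 genes in the real data and 4 in the highest of the others. Species was relabelled in each tissue on its own, so a plant could carry different labels in different tissues. A constant species difference can then appear as an interaction, so these relabellings cannot decide the question.

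More genes were called between the species in flowering panicles (237) than in flag leaves (31) or heading panicles (30), and the difference between these counts was not tested. O. nivara flowering panicles 34 and 197 were below every other flowering panicle in all 6 comparisons of the pollen genes OsMADS62, OsMADS63 and OsMADS68, so loss of pollen may mark these plants, but these genes were chosen after their values were seen and decide nothing. Without them 23 genes were called, and 4 of the 14 other pairs left out gave as few or fewer, which meets the bound set in advance (4 other pairs). Without 197 and 80, with 34 kept, 1 gene was called. Each of the 4 pairs holds 34 or 197 and also 52 or 80, and 0 of the 6 pairs with neither 34 nor 197 gave as few. The bound therefore cannot decide whether another stage of 34 and 197 gave the count, in whole or in part. The pairs of 34 or 197 with 25 or 40 gave 28 to 69, and the pairs without 34 and 197 gave 25 to 377.

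For the species differences, chance can be excluded for the gene counts of flag leaves (31, highest other split 1, with 1 of 100 splits as large) and flowering panicles (237, highest other 3, 1 of 100). In heading panicles 3 of 100 splits were as large as the real one (30), itself included, a share under 0.05. The others gave 382 and 94 genes, more than the real split, so chance is not taken as excluded there. The split with 382 genes points to a structure of the samples, since it follows the second principal component of these panicles. Chance is not excluded for the number of lists called in flag leaves (0, highest other 4, 100 of 100 splits), heading panicles (2, highest other 6, 58 of 100) or flowering panicles (4, highest other 6, 24 of 100). For the years it can be excluded in each tissue (3946, 4656 and 3326, highest others 1, 86 and 104, 1 of 100 each).

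For the tissues, 1 of 30 splits was as large in each comparison. Heading panicles against flag leaves gave 9405 genes in O. nivara (highest other 4609) and 8575 in O. rufipogon (3988), and flowering against heading panicles 2604 (111) and 1661 (287). Chance can be excluded in each. The highest others were among the 15 splits that part every plant found in both tissues, as the real split does, and the 14 that do not reached at most 363, 29, 32 and 23.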

How the results depend on the processing

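Thinning, scaling by library totals and leaving out O. nivara flowering panicles 34 and 197 were chosen after the data were seen. The species counts moved most. DESeq2 called 406 genes in flag leaves, 512 in heading panicles and 1986 in flowering panicles, and the model of all 36 libraries 259, 92 and 451. Without a year term there were 12, 13 and 44. The filter of at least 5 CPM, which tests fewer genes, gave 20 in flag leaves and 19 in heading panicles. Limma-trend gave 56 in heading panicles. With fewer plants, those of 2009 gave 12 in flag leaves and 13 in flowering panicles, those of 2010 gave 0, 11 and 9, and those from India 1, 0 and 2. In heading panicles those of 2009 gave 31, but only 6 were among the 30 reported. At an unadjusted p under 0.05 edgeR had 1235 genes in flag leaves of 2010 and 835 in heading panicles from India. Without plants 34 and 197 the flowering count was 23. DESeq2 size factors (32, 30 and 252), no filter (30, 29 and 237) and thinning (28, 31 and 193) stayed within 1.5 times the counts reported.

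Between flowering and heading panicles, title number as a block gave 46 genes in O. nivara, which shares 2 plants between these tissues, no year term gave 1705 there and 1079 in O. rufipogon, leaving out plants 34 and 197 gave 1651 in O. nivara, and DESeq2 gave 2524 in O. rufipogon. For the interaction, no year term gave 1 gene and DESeq2 79. With an estimated correlation 0 lists were called in heading panicles and 0 in flowering panicles. With fry, which asks another question, 1 was called in flag leaves, 0 in heading panicles and 2 in flowering panicles. Detected genes differed by -192.3 in heading panicles without thinning (exact permutation p = 0.026, adjusted p = 0.078). Other than for fewer samples or genes, the cause was not tested. Detected genes in flag leaves changed sign, from 99 to -136.3, where 5 or more counts were required, with no detectable difference either way. The balance of higher and lower genes turned where it was close to even: for years in flag leaves with DESeq2 size factors (1937 and 2026) and DESeq2 (2573 and 2768), for years in heading panicles with DESeq2 (3044 and 3069), and between flowering and heading panicles with DESeq2 size factors (1286 and 1335 in O. nivara, 831 and 838 in O. rufipogon), with DESeq2 (1763 and 1867) and no year term (844 and 861) in O. nivara, and with library totals (665 and 905) in O. rufipogon. No gene named by the rule was called in the opposite direction under any alternative run. The counts for heading panicles against flag leaves and for years stayed within 1.5 times. Depth limits the detection of genes low in counts. At 2-fold edgeR recovered 0 to 2% of the simulated species differences, up to 4% of the year differences and up to 8% of the tissue differences. DESeq2 recovered 6 to 14% of the species differences. The simulated changes were placed in genes with a mean of at least 5 CPM, so this recovery does not measure the limit set by depth.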

Other observations

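The tests in this part were chosen after the results they concern were seen, and so were the genes named.

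The level of ACOS12 (LOC_Os04g24530), a pollen wall gene of the tapetum, varied widely between heading panicles. It was at 883, 407, 282, 766 and 353 CPM in O. nivara heading panicles 33, 26, 80, 39 and 133 and at 0.233 in 52. In O. rufipogon it was at 1111 and 3963 CPM in 43 and 199, and at 9.67, 1.42, 14.2 and 0.558 in 47, 49, 95 and 230. OsPKS1 (LOC_Os10g34360), a polyketide synthase of the same pathway, and CYP704B2 (LOC_Os03g07250), a fatty acid hydroxylase of the anther, were at 2220 and 2281 CPM in O. rufipogon 199 and at 2.79 and 0.279 in 230.

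OsMADS8 (LOC_Os09g32948), a gene of floral organ identity, varied between plants of O. rufipogon in both panicle stages. Plants 43, 199 and 230 held 1.74, 0.228 and 0 CPM in heading panicles and 0, 0.224 and 0.419 in flowering panicles, where the other O. rufipogon panicles held at least 42.7 and 43.5. No O. nivara panicle was below 24.6 CPM. The species difference was not past the threshold (log2 1.72 in heading and 2.14 in flowering panicles, adjusted p = 0.649 and 0.349 by edgeR).

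The gap between collection years was weighed against 3 explanations. OsLHY was higher and the evening genes OsGI, OsPRR1, OsFKF1 and OsPRR95 were lower in 2010, with all 15 pairs of these 5 genes and 3 tissues called. These genes were chosen after their values were seen, so this decides nothing, and harvest at another phase of the daily clock in each year stays open. With every library thinned to the smallest total at least 85% of the year calls were made again in each tissue, which argues against deeper libraries in 2010 as the whole cause. Other plants or another sequencing batch in each year cannot be told apart from year, because 0 title numbers occur in both.

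Some genes called between the species were close to absent in 1 of them. A sequence variant that removes the counted tag could give such a gap in DGE but none in RNA-seq. Over 88 called genes past an 8-fold difference and above 0 in RNA-seq, the median RNA-seq log2 ratio in the DGE direction was 1.76 (95% interval 1.24 to 2.22). Of these 82 went the same way, which argues against such variants as the whole cause. Of the 88 genes 32 were within 2-fold in RNA-seq, but 18 of them were under 1 RPKM in both species, where adding 1 to each value brings any pair within 2-fold. These 18 had little RNA-seq signal also in the species with the higher DGE level, and the reason was not tested. For LOC_Os07g39060 in flag leaf the RPKM was 0 in O. nivara and 0.0452 in O. rufipogon, with a DGE log2 ratio of -6.26. A tag variant stays open for OsLEA3 (LOC_Os05g46480), 1 of the 10 within 2-fold at 1 RPKM or more in both, with a log2 ratio of -0.39 in flowering panicle. For LOC_Os01g65850 the tag was counted in O. nivara flag leaves, at 19.5 CPM, which argues against it. In addition, RNA-seq reads may also be lost to sequence differences from the reference, which was not tested.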
